A study of Mus musculus with 10 samples.

How the data were processed

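RNA sequencing measured gene expression in 10 libraries of mouse erythroblasts, the dividing and maturing precursors of red blood cells. The cells came from spleens 11 days after 5-FU, a chemotherapeutic drug that depletes dividing blood precursors. Per the labels, erythroblasts were isolated with a Miltenyi Biotec bead kit, RNA was extracted with Trizol, and libraries were made with a VAHTS Universal RNA-seq kit for Illumina sequencing. The labels give 4 genotypes: wild type (n = 2), mice lacking the miR-144/451 microRNA cluster (miR-144/451-null, n = 2), mice lacking Nrf2 (Nrf2-null, n = 3), and mice lacking both (double-null, n = 3). They give C57BL/6 as the strain of each library. They number the libraries within a genotype without saying which mouse each came from, so the p-values measure the spread between these libraries.

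The authors deposited a table of raw counts for 53465 Ensembl genes and, for each library, a file of normalized values. The deposited FPKM values had been made by dividing each count by 1 length per gene and by the library total, as the values show: all 196970 compared values equalled that quotient to within 0.1%. The FPKM values were used for that comparison alone, and every fit used the counts. The submitters' processing notes name CASAVA, Bowtie2 2.2.3, HISAT2 2.1.0, TopHat2 and the build mm9, without the role of each. The counting tool, the annotation and the strand setting are not given in the sources used here. Reads from overlapping or antisense genes were therefore not told apart, and for some genes the share of 31-mers found in another gene is given. Symbols, chromosomes and UTRs came from GENCODE M21, an annotation of a later build than mm9, through the Ensembl identifiers, of which 99.6% matched. No coordinates are printed.

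Library totals ranged from 13087827 to 15131036 counts, and globin genes took 7.08% to 12.18% of them. Replicates differed by more than sampling noise in each pair, with a chi-square per degree of freedom of 17.3 to 30.4, so none was counted as a repeat of another. Folds against a group with no count use a floor of 3 counts per library. Such floors and counting intervals cover counting error only.

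All 10 libraries entered a single fit in R 4.3.3 with edgeR 4.0.16, with a coefficient for each genotype, TMM factors and the robust quasi-likelihood test (two-sided). The filterByExpr filter left 14110 genes, and the fit had 6 residual degrees of freedom. A gene passed the threshold at a Benjamini-Hochberg adjusted p under 0.05. Levels are normalised CPM (counts scaled to a common library size with the TMM factors), as mean ± SD, and log2 fold changes carry their standard error (SE). The contrasts were each null genotype against wild type, the double-null against each single null, and the interaction. The last asks whether loss of the cluster had a different effect with and without Nrf2.

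A set of 20 gene lists, 8 lists of cell type markers and a list of 5 sex-linked genes was fixed before the data were examined, as were the comparisons, the tests and the rule for naming genes. Each list was compared with all other tested genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. The 20 gene lists were adjusted together within a comparison, and so were the marker and sex-linked lists. The correlation was also estimated from each list, and fry served as a further test. The named genes were the targeted genes, up to 10 genes per direction and comparison, and up to 4 members of each list with the smallest p. The genes named by size had an adjusted p under 0.05, a mean of at least 5 CPM, no overlap between the groups and no predicted-gene name, and were taken in order of log2 fold change. Some genes that the rule names are not reported here.

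Seed sites were searched in the longest annotated 3' UTR of each gene, which existed for 11743 tested genes (83.2%). Genes with a 7-mer match to positions 2 to 8 of miR-144-3p or miR-451a were compared with genes without, within 20 bins of UTR length, by a two-sided permutation test of 100000 resamples. Other 7-mers of the same base composition found in at least 20 genes served as controls. Genes are not independent replicates, so this test describes the genes of these libraries.

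On simulated counts with 200 changed genes among 14110, the fit recovered 35% of 2-fold and 78% of 4-fold changes for miR-144/451-null against wild type. It recovered 43% and 80% for double-null against Nrf2-null, with no call of the wrong sign in either. Unchanged genes made up 14 of 127 calls in the first simulation, more than the 5% aimed at, and 5 of 128 in the other. The list test called the shifted list and none of 19 unshifted lists. Genes were simulated independently of each other, so this does not show how the list test behaves where genes are correlated. A shift of 0.3 planted in the genes with a seed site was found as 0.317 for miR-144-3p and 0.279 for miR-451a.

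Alternatives were DESeq2 1.42.0, RLE factors, no scaling factors, removal of globin genes, all genes with a count, a filter at 1 CPM in 2 libraries, fits of the compared groups alone, the replicate number as a block, limma-voom with sample weights, 8-mer seed sites and each library left out in turn. Counts of Xist and of Y-linked genes showed that the sexes were not balanced across genotypes. A term for sex and a fit without X- and Y-linked genes were therefore added after the data had been seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 served for the seed sites and matplotlib 3.10.9 for the figures.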

Results

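Gene expression was compared in 10 libraries of mouse spleen erythroblasts of 4 genotypes, 11 days after 5-FU: wild type (n = 2), miR-144/451-null (n = 2), Nrf2-null (n = 3) and double-null (n = 3). The miR-144/451 cluster encodes microRNAs that are abundant in erythroid cells, and Nrf2, the product of Nfe2l2, is a transcription factor that switches on antioxidant genes. Libraries held 13087827 to 15131036 counts, and 14110 genes were tested. By Xist and Y-linked counts, both wild type libraries and double-null replicate 3 came from females and the other 7 libraries from males. The comparisons of either single null with wild type therefore coincide with a comparison of males with females.

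The targeted genes were examined first. Mir144 had 29 counts over the wild type libraries and 38 over the Nrf2-null libraries, and 0 in each miR-144/451-null and double-null library. It was at least 5.37-fold lower in miR-144/451-null than in wild type and at least 4.21-fold lower in double-null than in Nrf2-null. Mir451a had 0 counts in every library, so the sequencing did not measure it. Nfe2l2 stood at 60.8 ± 3.8 CPM in wild type, 83.9 ± 3.17 in miR-144/451-null, 50.6 ± 4.78 in Nrf2-null and 54.8 ± 6.99 in double-null. A count over the whole gene cannot show the deleted part, so it checks nothing about the Nrf2 genotype. Pir, which encodes pirin and is a known Nrf2 target, stood at 38.2 ± 14.9 CPM in wild type and 28.9 ± 6.69 in miR-144/451-null. It stood at 11.2 ± 0.869 in Nrf2-null and 7.12 ± 0.478 in double-null. Pir was not among the genes fixed beforehand for checking the labels, so its values are no independent test of the Nrf2 genotype.

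**Figure D1:**
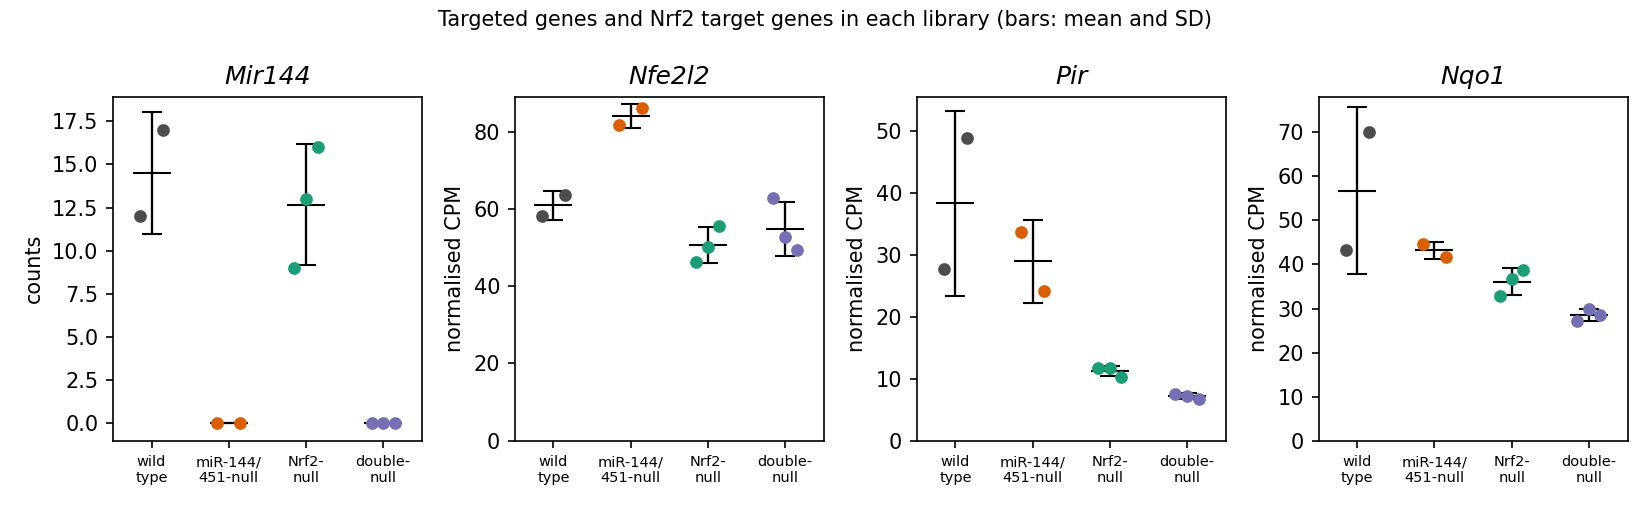
Counts of Mir144 and normalised CPM of Nfe2l2, Pir and Nqo1 in each library (points) of the 4 genotypes, with the mean and SD as bars. Mir144 was at 0 in the 5 libraries without the cluster, and Pir was lower in the Nrf2-null and double-null libraries than in the others.

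Loss of the cluster where Nrf2 is present (miR-144/451-null against wild type) moved 653 genes past the threshold, 338 higher and 315 lower, 284 of them at least 2-fold. Camera with its preset correlation called the cell cycle, red cell membrane and erythroid transcription factor lists lower and the reported microRNA targets higher, and with an estimated correlation it called no list. Of the cell cycle list, 13 of 32 genes fell (20 when adjusted over the list alone), with a median log2 fold change of -0.59. They included the kinetochore gene Cenpf (log2 fold change -1.32 ± 0.20 SE, adjusted p = 0.00672), the mitotic kinase Aurka (-0.77 ± 0.13, adjusted p = 0.00976), cyclin A2 (Ccna2, -0.96 ± 0.17) and Cdk1 (-0.98 ± 0.19). Camera called the list lower (adjusted p = 1.9e-12), with an adjusted p = 0.558 with an estimated correlation. Of 21 red cell membrane genes, 3 fell, among them dematin (Dmtn, -0.93 ± 0.20) and glycophorin C (Gypc, -0.75 ± 0.19). Adjusted over the list alone, 14 fell (camera adjusted p = 1.03e-07; adjusted p = 0.574 with an estimated correlation). Among 18 erythroid transcription factors, Klf1, a master regulator of globin and red cell genes, fell by 0.83 ± 0.20 and Klf3 by 1.23 ± 0.25, 5 fell when adjusted over the list alone, and camera gave adjusted p = 0.0118 (adjusted p = 0.574 with an estimated correlation).

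Of 10 reported miR-144 and miR-451 targets, 4 rose (6 when adjusted over the list alone): Ywhaz, a 14-3-3 adaptor (0.94 ± 0.14, adjusted p = 0.00701), Cmtm6 (0.80 ± 0.15), Cab39 (0.70 ± 0.15) and the small GTPase Rab14 (0.62 ± 0.15). Camera gave adjusted p = 0.0011 for this list and fry adjusted p = 0.0041, with an adjusted p = 0.288 with an estimated correlation. Of the 11 list calls of camera in this comparison, fry kept 2, these targets and cell cycle. In the oxidative phosphorylation list 4 of 28 genes rose, among them Uqcrc2 (0.79 ± 0.16), Sdhc (0.77 ± 0.19) and Cox5a (0.80 ± 0.20), 7 when adjusted over the list alone (camera adjusted p = 0.00202; adjusted p = 0.733 with an estimated correlation). Of 15 Epo-Stat5 and survival genes, the kinase gene Pim2 fell by 1.14 ± 0.21, and 2 fell when adjusted over the list alone (camera adjusted p = 0.0396; adjusted p = 0.582 with an estimated correlation). Cpox, an enzyme of heme synthesis, and Ncoa4, the receptor that delivers ferritin for breakdown, fell by 0.77 ± 0.17 and 1.21 ± 0.20. The transferrin receptor gene Tfr2 and the autophagy gene Gabarapl1 rose by 0.76 ± 0.17 and 1.17 ± 0.24. Camera also called higher the proteasome (median 0.24) and ribosomal protein (0.16) lists and lower the interferon-response list (-0.54) and the T cell markers (-0.79; estimated-correlation adjusted p from 0.733 to 0.967). No member of these 4 lists passed edgeR's threshold. At an unadjusted p under 0.05, 8 proteasome genes were higher and 1 T cell marker lower, and DESeq2 called 2 proteasome genes. The interferon-response median rested on miR-144/451-null replicate 3, without which it was -0.17 and not called (-1.31 without replicate 1). Leaving out wild type replicate 1 ended the calls of proteasome (0.10), oxidative phosphorylation (0.05), ribosomal proteins (0.12) and T cell markers (-0.46). Leaving out wild type replicate 3 ended those of erythroid transcription factors (-0.16) and Epo-Stat5 genes (-0.10) and left red cell membrane at -0.32. Without miR-144/451-null replicate 1 the proteasome (0.13), B cell (-0.61) and T cell (-0.58) calls ended, and without replicate 3 those of erythroid transcription factors (-0.35) and Epo-Stat5 genes (-0.40), while B cell and T cell markers moved to -1.49 and -1.25. The Epo-Stat5 and T cell calls also ended without Nrf2-null replicate 2 or 3 and with a term for sex, and the Epo-Stat5 call with the replicate block (-0.63). The term for sex moved the oxidative phosphorylation (0.45), ribosomal protein (0.45), proteasome (0.39) and erythroid transcription factor (-0.46) medians further from 0. Without scaling factors the oxidative phosphorylation median was 0.33, ribosomal proteins 0.28 and erythroid transcription factors -0.18. The 28 Nrf2 target genes had a median of 0.18, and Tkt, an enzyme of the pentose phosphate pathway, rose (0.60 ± 0.15, adjusted p = 0.0472; camera adjusted p = 0.166 for the list).

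Genes with the largest changes included Myo15, an unconventional myosin, at 29.5 ± 0.169 CPM in miR-144/451-null against 3.12 ± 1.08 in wild type. Bex4 stood at 169 ± 15.9 against 30.6 ± 2.13, and the interferon-inducible GTPase genes Irgm2 and Igtp were 4.49-fold and 3.94-fold higher. Myo15, Irgm2 and Igtp were also higher than in wild type in Nrf2-null, which keeps the cluster. Their rise was therefore not particular to loss of the cluster. Csf2rb2, a β chain of the interleukin-3 receptor, was 7.46-fold higher, though 28.6% of its 31-mers are shared with Csf2rb. Eps8l1, an actin regulator, was 57.5-fold lower, Artn, a neurotrophic ligand, 7.6-fold, the glucose transporter gene Slc2a4 4.08-fold and Mxd3, a relative of the Myc antagonists, 3.94-fold lower. B cell markers lay lower alongside these lists, with a median of -0.95 over 11 genes (camera adjusted p = 0.00174; adjusted p = 0.746 with an estimated correlation). None of them passed edgeR's threshold, 5 were lower at an unadjusted p under 0.05, and DESeq2 called 2 lower. With a term for sex, which rests on the double-null libraries alone, 1 gene remained past the threshold (Rps19-ps6, a pseudogene). The count was 40 without wild type replicate 3, 81 without miR-144/451-null replicate 1, 200 without wild type replicate 1, 331 without miR-144/451-null replicate 3 and 390 without Nrf2-null replicate 1. Of 39 calls of genes selected from the naming rule for this comparison, 34 were lost without wild type replicate 3, 34 without miR-144/451-null replicate 1, 23 without miR-144/451-null replicate 3 and 22 without wild type replicate 1, and none changed sign. Without scaling factors the split was 497 higher and 247 lower.

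**Figure D2:**
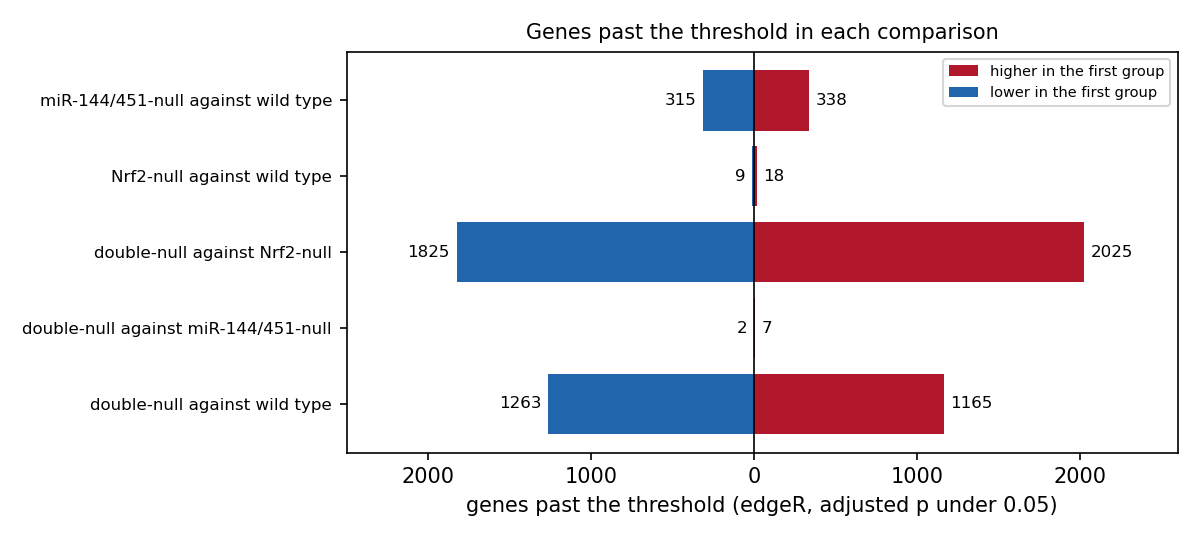
Numbers of genes past the threshold in each comparison (edgeR, adjusted p under 0.05), with genes higher in the first-named genotype to the right and lower to the left. Double-null against Nrf2-null had 2025 higher and 1825 lower genes, and double-null against miR-144/451-null had 7 and 2.

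Loss of the cluster where Nrf2 is absent (double-null against Nrf2-null) moved 3850 genes past the threshold, 2025 higher and 1825 lower, 1631 of them at least 2-fold. Camera with its preset correlation called the cell cycle, red cell membrane and interferon-response lists lower and the proteasome, oxidative phosphorylation and ribosomal protein lists higher, and with an estimated correlation it called no list. In the cell cycle list 25 of 32 genes fell (30 adjusted over the list alone; median -0.92), among them Cenpf (-1.92 ± 0.17, adjusted p = 5.32e-05), Aurka (-1.26 ± 0.11), Cdk1 (-1.60 ± 0.15) and Aurkb (-1.52 ± 0.15). Camera gave adjusted p = 2.14e-13 and fry adjusted p = 0.00078 (adjusted p = 0.493 with an estimated correlation). Of the 14 list calls of camera, fry kept 9. Of 21 red cell membrane genes 10 fell (13 adjusted over the list alone), including the aquaporin gene Aqp1 (-0.95 ± 0.19), Dmtn (-0.83 ± 0.16) and Xk (-0.73 ± 0.15; camera adjusted p = 1.74e-04, adjusted p = 0.569 with an estimated correlation). Among the erythroid transcription factors 7 of 18 fell and 1 rose. Klf1 (-1.10 ± 0.16), Klf3 (-1.29 ± 0.20), Gfi1b (-1.14 ± 0.18) and Klf13 (-0.74 ± 0.18) fell, while camera did not call the list (adjusted p = 0.0659). Of 12 iron genes 4 fell, among them the ferrireductase gene Steap3 (-0.76 ± 0.14), ferroportin (Slc40a1, -0.84 ± 0.19) and the iron importer gene Slc11a2 (-0.72 ± 0.15), and Tfr2 rose (0.95 ± 0.14; camera adjusted p = 0.402).

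Of 31 proteasome genes 20 rose and none fell (24 adjusted over the list alone; median 0.57), for example Psmb3 (0.99 ± 0.13), Psmb4 (0.93 ± 0.12) and Psmd6 (0.90 ± 0.12; camera adjusted p = 2.29e-08, adjusted p = 0.569 with an estimated correlation). Of 28 oxidative phosphorylation genes 18 rose, with Ndufb5 at 1.37 ± 0.20, Uqcrc2 at 1.25 ± 0.14 and Cox5a at 1.21 ± 0.17 (19 adjusted over the list alone; camera adjusted p = 1.11e-06, adjusted p = 0.569 with an estimated correlation). Transcripts encoded by the mitochondrial genome made up 1.22 to 1.41% of counts in the double-null libraries against 0.84 to 1.02% in Nrf2-null, and 1.58 and 1.8% in miR-144/451-null against 1.13% in both wild type libraries. Of 84 ribosomal protein genes 29 rose, 41 adjusted over the list alone (median 0.40; camera adjusted p = 7.78e-09, adjusted p = 0.569 with an estimated correlation). Of the 10 reported targets of the cluster 6 rose (7 adjusted over the list alone), with Rab14 at 0.91 ± 0.13, Cmtm6 at 0.83 ± 0.12, Ywhaz at 0.76 ± 0.12 and Cab39 at 0.73 ± 0.12 (camera adjusted p = 0.00276, adjusted p = 0.455 with an estimated correlation). Among 28 Nrf2 target genes 8 rose and 1 fell although these libraries lack Nrf2, including the peroxiredoxin gene Prdx1 (1.12 ± 0.16), Tkt (0.86 ± 0.12), the exporter gene Abcc4 (0.83 ± 0.12) and sulfiredoxin (Srxn1, 1.99 ± 0.44). Camera did not call that list (adjusted p = 0.0659). Of 13 heat shock genes 5 rose and 1 fell, with Hspa1b at 2.17 ± 0.33, its co-chaperone gene Bag3 at 1.79 ± 0.29 and Dnajb1 at -0.99 ± 0.15 (camera adjusted p = 0.00944, adjusted p = 0.569 with an estimated correlation).

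Of 17 measured identifiers for 16 glycolysis genes, 6 rose, including Hk1 (0.72 ± 0.14), Gapdh (0.91 ± 0.19) and Tpi1 (0.90 ± 0.23). Aldoa has 2 identifiers, of which the first rose and the other fell, so its reads are uncertain (camera adjusted p = 0.046, adjusted p = 0.569 with an estimated correlation). Of 25 interferon-response genes 16 fell (21 adjusted over the list alone; median -1.53), among them Rtp4 (-4.43 ± 0.80), Usp18 (-3.02 ± 0.53), Oasl1 (-2.75 ± 0.49) and Stat2 (-1.66 ± 0.29; camera adjusted p = 6.62e-08, adjusted p = 0.569 with an estimated correlation). B cell markers fell with them, 9 of 11 (median -1.81), including Cr2 (-2.45 ± 0.46) and Ms4a1 (-2.22 ± 0.41; camera adjusted p = 1.45e-04, adjusted p = 0.841 with an estimated correlation). Macrophage markers had a median of -1.39, NK cell markers -1.52, T cell markers -0.87 and neutrophil markers 0.85 (estimated-correlation adjusted p = 0.841, 0.841, 0.841 and 0.842). Without Nrf2-null replicate 3, which stood apart, the macrophage median was -0.76, and the neutrophil (0.45), T cell (-0.76), NK cell (-1.57) and glycolysis (0.35) calls ended. The T cell call also ended without double-null replicate 1 (-0.46), the glycolysis call without double-null replicate 2 (0.41), the neutrophil call without double-null replicate 1 or 2 or wild type replicate 3, and the NK cell call without any 1 of 5 other libraries. Without double-null replicate 2 the T cell and NK cell medians moved to -1.48 and -2.63, and without Nrf2-null replicate 2 the neutrophil median moved to 1.65. The NK cell and neutrophil calls ended with globin genes removed, and the NK cell call with a term for sex (-1.27). Single genes with large changes were the neuronal tubulin gene Tubb3 (17.1 ± 7.88 against 0.619 ± 0.343 CPM), Bex4 (246 ± 32.2 against 22.8 ± 5.71), Podxl (106 ± 56 against 8.89 ± 7.51), Mxd3 (15.1 ± 3.89 against 116 ± 23.4) and Artn (3.29 ± 1.15 against 26.7 ± 6.68). In the 7 male libraries alone 2595 genes passed the threshold, 1504 higher and 1091 lower.

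**Figure D3:**
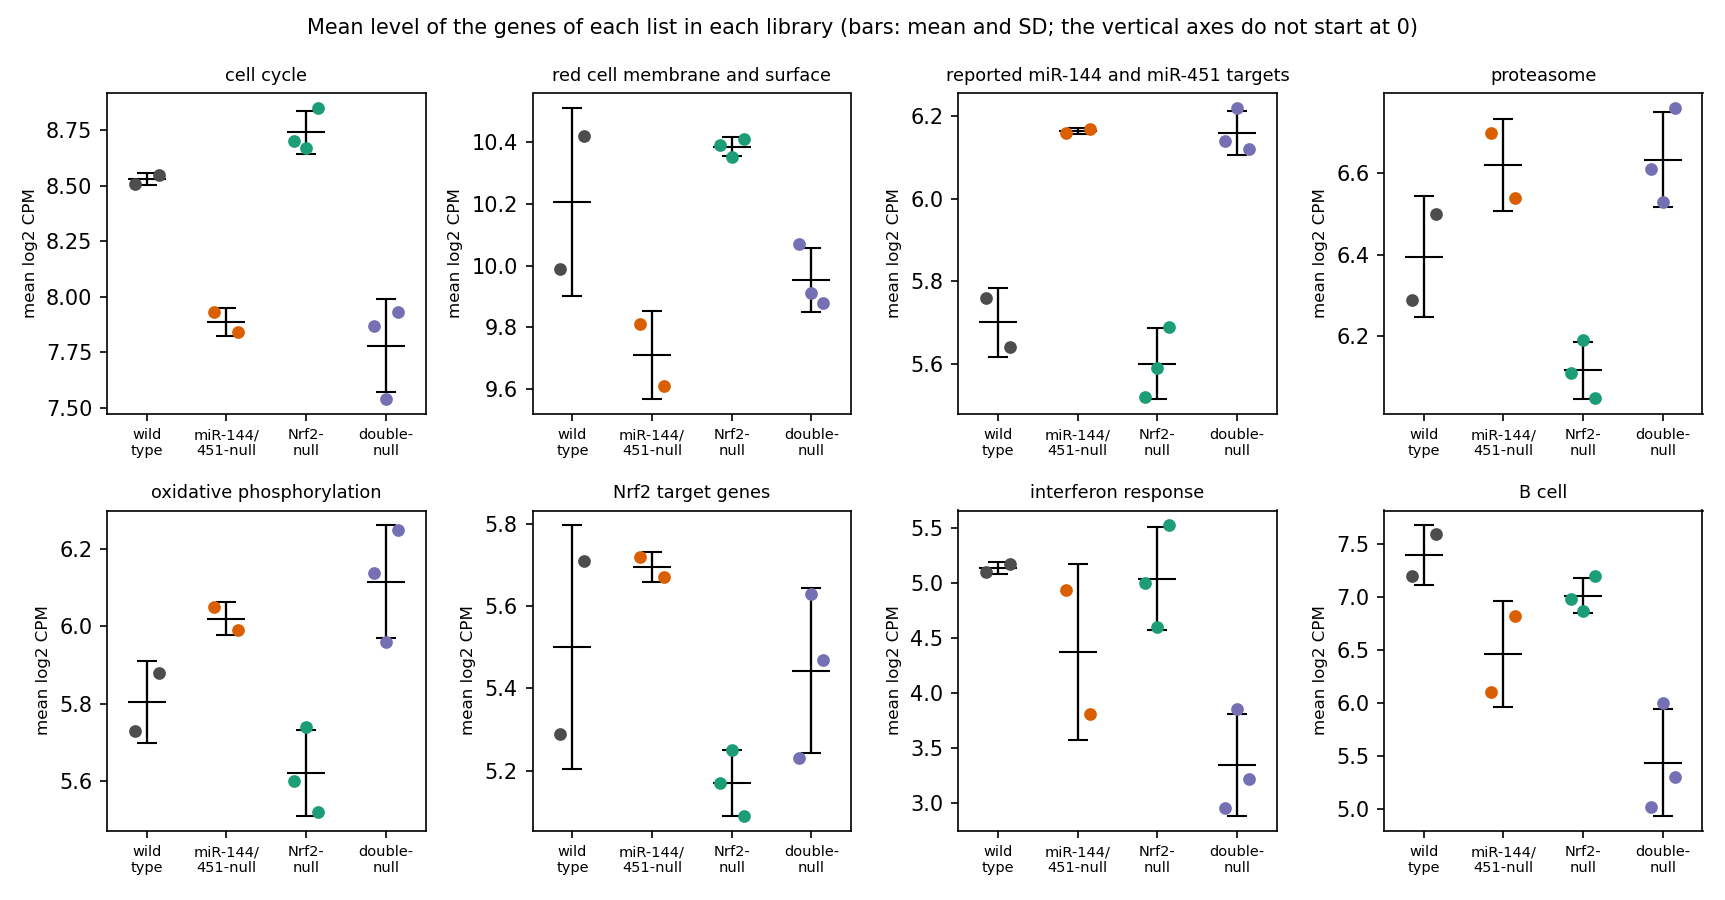
Mean log2 CPM of the genes of 8 lists in each library (points) of the 4 genotypes, with the mean and SD as bars and vertical axes that do not start at 0. In the 5 libraries without the cluster the cell cycle list lay between 7.54 and 7.93, and in the other libraries between 8.51 and 8.85.

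Whether the effect of losing the cluster carried over between genotypes was examined with the comparisons that share no library. Of the 653 genes called in miR-144/451-null against wild type, 643 (98.5%) had the same sign in double-null against Nrf2-null, against 71.6% of genes called in neither. Among them 315 were higher and 294 lower past the threshold in both comparisons, where independent lists would share 48.5 and 40.7. None was called in opposite directions. The higher genes had a median log2 fold change of 0.89 in the comparison that selected them and 1.02 in the other, and the lower genes -1.03 and -1.24. In the reverse direction the medians shrank. Genes called in double-null against Nrf2-null went from 0.78 to 0.48 and from -1.09 to -0.63 in miR-144/451-null against wild type. The genes called in neither lack a call by selection, so 71.6% is not a neutral background.

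**Figure D4:**
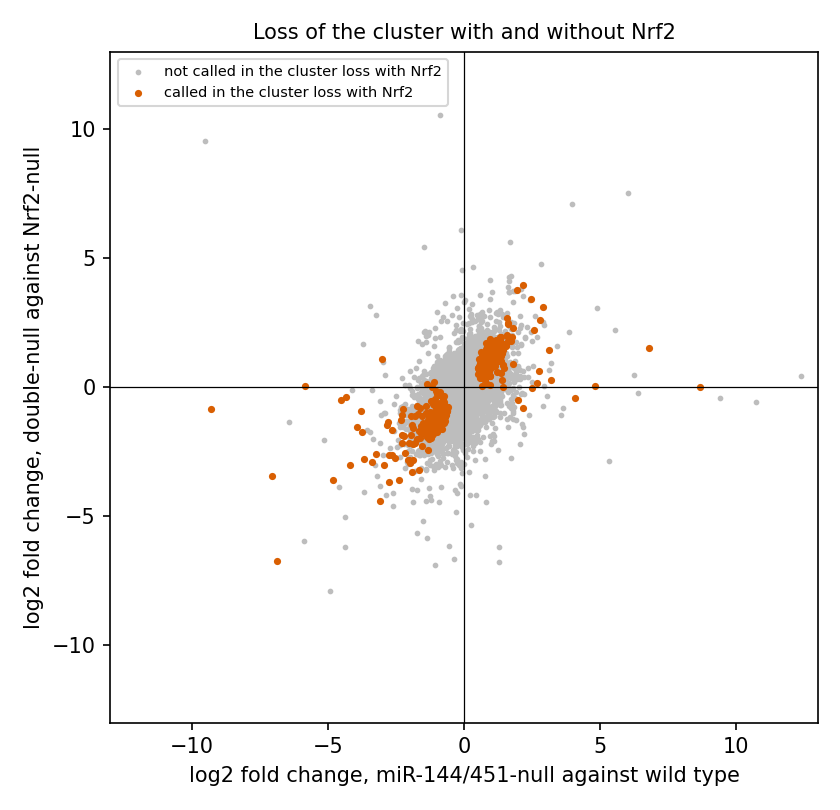
Log2 fold change of each tested gene on loss of the cluster with Nrf2 (horizontal) and without Nrf2 (vertical), with the 653 genes called in the first in orange. Of these, 643 lie in the quadrants of equal sign.

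Genes with a site for the deleted microRNAs in their 3' UTR lay higher wherever the cluster was lost. The 227 genes with a miR-451a 7-mer had a mean log2 fold change 0.257 ± 0.043 (SD over permutations) above genes without in miR-144/451-null against wild type (permutation test, adjusted p = 3.3e-05). The difference was 0.224 ± 0.054 in double-null against Nrf2-null (adjusted p = 6e-05) and 0.287 ± 0.057 in double-null against wild type (adjusted p = 5e-05). The 1558 genes with a miR-144-3p 7-mer lay 0.086 ± 0.019 and 0.116 ± 0.023 higher (adjusted p = 3.3e-05 each, from the smallest p that the permutations can give, 1e-05). Controls were ranked by the difference divided by its permutation SD. In miR-144/451-null against wild type and double-null against Nrf2-null, all of the 629 control 7-mers for miR-451a ranked lower. For miR-144-3p, 99.8% and 100% of the 419 controls did. In the comparisons where the cluster did not differ, the values were 0.063 ± 0.04 and 0.03 ± 0.038 for miR-451a and -0.024 ± 0.017 and 0.006 ± 0.016 for miR-144-3p (adjusted p from 0.16 to 0.72). In Nrf2-null against wild type miR-451a ranked above 94.9% of its controls and miR-144-3p above 2.4%. In double-null against miR-144/451-null these shares were 77.9% and 47.5%. Among the reported targets, the miR-451a 7-mer occurs in Ywhaz and Cab39 and the miR-144-3p 7-mer occurs in Nfe2l2, among others. With 8-mer sites the miR-451a difference in double-null against Nrf2-null was 0.162 (45 genes, adjusted p = 0.24).

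**Figure D5:**
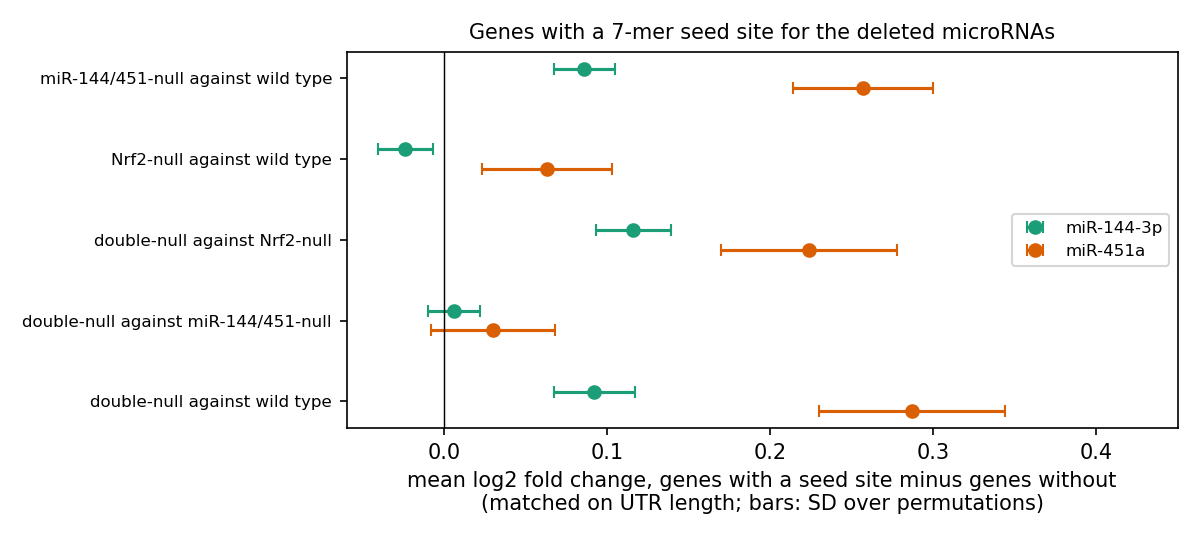
Length-matched difference in mean log2 fold change between genes with and without a 7-mer seed site, for each microRNA and comparison, with the SD over permutations as bars. For miR-451a it was 0.257, 0.224 and 0.287 where the cluster differed, and 0.063 and 0.03 where it did not.

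Loss of Nrf2 alone (Nrf2-null against wild type) moved 27 genes past the threshold, 18 higher and 9 lower, and Nrf2 target genes had a lower median. Pir, which the fixed list of Nrf2 targets does not hold, fell by 1.77 ± 0.24 (adjusted p = 0.00914). It lies on the X chromosome and was no longer called with a term for sex (-1.92, adjusted p = 0.484), without wild type replicate 3 (-1.31, adjusted p = 0.162), without Nrf2-null replicate 1 (adjusted p = 0.057) or 2 (adjusted p = 0.0646), or with the replicate block (adjusted p = 0.0617). Of the 28 genes of the Nrf2 target list 0 passed edgeR's threshold over all genes, 11 were lower and 3 higher at an unadjusted p under 0.05, and DESeq2 called 2 lower. Adjusted over the list alone 3 were lower, and the median was -0.33 (camera adjusted p = 0.0062, adjusted p = 0.828 with an estimated correlation). Without wild type replicate 3 the median was -0.13 and the list was not called, without wild type replicate 1 it was -0.54, and with a term for sex it was -0.26 and not called. Glutathione reductase (Gsr) stood at -0.89 ± 0.20, Srxn1 at -2.19 ± 0.47, Nqo1 at -0.65 ± 0.18 and thioredoxin reductase (Txnrd1) at -0.58 ± 0.18. Camera also called lower the proteasome (median -0.30), heat shock (-0.59), oxidative phosphorylation (-0.20) and ribosomal protein (-0.10) lists. It called higher the cell cycle (0.21), red cell membrane (0.13) and stress response (0.37) lists and the macrophage markers (1.51, adjusted p = 0.864 with an estimated correlation). None of these calls held with an estimated correlation (adjusted p from 0.828 to 0.903 for the gene lists), and the ribosomal protein gene Rplp0 (-1.17 ± 0.18) was the sole member of these lists past edgeR's threshold. At an unadjusted p under 0.05, 14 proteasome and 8 heat shock genes were lower and 4 cell cycle genes and 7 macrophage markers higher, while DESeq2 called 0 of them except 1 heat shock gene. Fry kept 0 of these 9 list calls, Nrf2 targets included, and the term for sex kept 3, with cell cycle at 0.44 and macrophage markers at 2.62. The oxidative phosphorylation (0.02) and ribosomal protein (0.22) medians changed sign, and the Nrf2 target, red cell membrane (0.05), stress response (0.28) and proteasome (-0.10) calls were lost. Leaving out wild type replicate 1 turned the red cell membrane median (-0.07) and ended the heat shock (-0.28) and stress response (0.31) calls. Leaving out wild type replicate 3 moved red cell membrane to 0.42 and proteasome to -0.18 and ended the oxidative phosphorylation (-0.14) and ribosomal protein (-0.06) calls. The ribosomal protein call also ended without Nrf2-null replicate 3 (0.01) or miR-144/451-null replicate 3 (-0.09) and with RLE factors (-0.08) or the replicate block (-0.11), and its median was -0.19 without Nrf2-null replicate 2. The stress response call ended without Nrf2-null replicate 1 (0.30) or 2 (0.28) and with the replicate block (0.26), and macrophage markers moved to 0.81 without Nrf2-null replicate 3. Without scaling factors the cell cycle median was 0.10, red cell membrane 0.05 and ribosomal proteins -0.20.

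Genes that rose included Cwc22, a splicing factor on chromosome 2 like Nfe2l2 (316 ± 13.5 against 26.4 ± 3.46 CPM), Myo15 (62.5 ± 11.7 against 3.12 ± 1.08), the pro-apoptotic gene Bcl2l11 (96.1 ± 17.6 against 32.9 ± 5.21), securin (Pttg1, 195 ± 23.6 against 45.9 ± 5.73), and Irgm2 and Igtp. Fgfrl1 (3.17 ± 0.891 against 46.3 ± 1.19), Idua (2.35 ± 0.438 against 10.3 ± 0.246), Lpin1, an enzyme of lipid synthesis (8.83 ± 1.2 against 36.5 ± 9.18), and Ublcp1, a phosphatase of the proteasome (35 ± 2.08 against 95.6 ± 11.4), fell. Fgfrl1 and Idua stood at 80.3 ± 4.31 and 14.7 ± 1.22 CPM in double-null, which lacks Nrf2 too. Their fall was therefore seen in the Nrf2-null libraries alone. Eif3j2 rose 5.95-fold, and 94% of its 31-mers are shared with Eif3j1, so its reads are uncertain. DESeq2 called 134 genes, a fit of all genes with a count 716, and the fit with a term for sex 12, of which 8 were among the 27. The count was 11 without wild type replicate 3, where 11 of 16 selected calls were lost, and 17 without Nrf2-null replicate 2, and the split was 14 higher and 11 lower without scaling factors.

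Loss of Nrf2 where the cluster is absent (double-null against miR-144/451-null) moved 9 genes past the threshold, 7 higher and 2 lower. Pir fell by 2.02 ± 0.24 (adjusted p = 0.0101), and its call was lost with a term for sex (-1.97, adjusted p = 0.0639) and without double-null replicate 1 (adjusted p = 0.051) or 3 (adjusted p = 0.0657). It was also lost with the replicate block (adjusted p = 0.0951), with limma-voom (adjusted p = 0.122) and in a fit of the 2 groups alone (adjusted p = 0.051). Cwc22 rose by 2.88 ± 0.15 (adjusted p = 9.69e-06) and Eif3j2 by 2.21 ± 0.24 (adjusted p = 0.00697). Of the 31-mers of Cwc22, 22.4% are shared with Gm13691, so its reads are uncertain too. Rps19-ps6 fell by 2.29 ± 0.26, and 78.2% of its 31-mers are shared with Rps19 and 99.5% with any other gene. It was high in miR-144/451-null alone (59.9 ± 2.12 CPM), against 8.76 ± 0.0636 in wild type, 7.97 ± 1.93 in Nrf2-null and 12.2 ± 4.03 in double-null. Its fall was therefore not particular to loss of Nrf2. Pir, Cwc22, Eif3j2 and Gm10031 were also called, in the same direction, in Nrf2-null against wild type. Nqo1 stood at 28.6 ± 1.4 against 43.2 ± 1.94 CPM (-0.59 ± 0.19, adjusted p = 0.326), and the 28 Nrf2 target genes had a median of -0.20 (camera adjusted p = 0.157). Camera called lower the interferon-response list (median -1.06), the B cell markers (-1.10) and the NK cell markers (-0.40). It called higher the red cell membrane (0.23), globin (0.55), heme (0.22), organelle clearance (0.36), stress response (0.39), Epo-Stat5 (0.43) and ribosomal protein (0.14, but -0.07 and not called without scaling factors) lists and the neutrophil markers (0.68). No member of these lists passed edgeR's threshold, and with an estimated correlation no list did (adjusted p = 0.788 for each gene list and from 0.806 to 0.858 for the markers). Fry kept 0 of the 11 list calls. Adjusted over the list alone, 6 interferon-response genes and 8 B cell markers were lower. The interferon-response median rested on miR-144/451-null replicate 1, without which it was -0.50 and not called. The neutrophil (0.17), NK cell (-0.90) and Epo-Stat5 (0.48) calls ended without that library too. Without miR-144/451-null replicate 3, 4 of the 11 list calls were kept, B cell markers moved to -0.66, and the red cell membrane (0.08), globin (0.53), heme (0.04), organelle clearance (0.17), stress response (0.24), Epo-Stat5 (0.31) and NK cell (-0.11) calls ended. Leaving out double-null replicate 1, 2 or 3 kept 8, 9 and 9 of the 11, leaving out Nrf2-null replicate 3 kept 10, and the heme (0.01) and NK cell (-0.66) calls ended without scaling factors. Other medians moved too: without scaling factors red cell membrane was at 0.03, organelle clearance 0.16, stress response 0.18, Epo-Stat5 0.22, globins 0.35 and neutrophil markers 0.45, all still called. The term for sex ended the ribosomal protein (0.03) and NK cell (-0.05) calls. The replicate block ended the Epo-Stat5 (0.34) and neutrophil (0.39) calls, left stress response at 0.25 and moved NK cell markers to -1.03. Other medians grew: globins (0.85) and red cell membrane (0.37) without miR-144/451-null replicate 1, neutrophil markers (1.60) without miR-144/451-null replicate 3, and NK cell markers (-1.71) and ribosomal proteins (0.22) without double-null replicate 2. At an unadjusted p under 0.05, 11 interferon-response genes and 9 B cell markers were lower, and DESeq2 called 2 and 4. DESeq2 called 175 genes in all and a fit of all genes with a count 743. The count was 78 without miR-144/451-null replicate 1, 31 without miR-144/451-null replicate 3, 17 without double-null replicate 2, 16 without Nrf2-null replicate 3 and 4 without double-null replicate 1.

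Loss of both (double-null against wild type) left 2428 genes past the threshold, 1165 higher and 1263 lower, 1218 of them at least 2-fold. Pir fell by 2.42 (edgeR, adjusted p = 0.000503). Its call was kept with the replicate block (-2.44, adjusted p = 0.0033) and with a term for sex (-2.52, adjusted p = 0.0149), which rests on the double-null libraries alone. Among female libraries Pir stood at 6.63 CPM in double-null replicate 3 and at 27.7 and 48.8 in wild type, without a test. Of 32 cell cycle genes 18 fell (19 adjusted over the list alone; median -0.84), with Cenpf at -1.68 ± 0.18, Aurka at -1.10 ± 0.12, Ccna2 at -1.20 ± 0.15 and the checkpoint kinase gene Bub1b at -1.03 ± 0.13 (camera adjusted p = 2.81e-10, adjusted p = 0.715 with an estimated correlation). Of the erythroid transcription factors 6 of 18 fell, 9 adjusted over the list alone, including Gfi1b (-1.38 ± 0.20), Klf3 (-1.03 ± 0.22) and Klf1 (-0.95 ± 0.18; camera adjusted p = 0.0412, adjusted p = 0.850 with an estimated correlation). Of the reported targets 5 of 10 rose, 6 adjusted over the list alone, with Rab14 at 0.88 ± 0.14, Ywhaz at 0.85 ± 0.13, Cmtm6 at 0.77 ± 0.14 and Cab39 at 0.75 ± 0.14 (camera adjusted p = 0.00876, adjusted p = 0.647 with an estimated correlation). The Nrf2 targets went both ways, with a median of 0.07 and a mean of -0.05: Nqo1 (-0.99 ± 0.18) and 1 more fell, while the autophagy adaptor gene Sqstm1 (1.11 ± 0.25), Prdx1 (0.66 ± 0.18) and Tkt (0.56 ± 0.14) rose (camera adjusted p = 0.758). The chaperone gene Hspa5, Herpud1 and Xbp1, all of the unfolded protein response, rose by 1.81 ± 0.46, 1.53 ± 0.34 and 1.20 ± 0.31, and camera did not call their list (adjusted p = 0.243). Of 25 interferon-response genes 13 fell (22 adjusted over the list alone; median -1.63), with Rtp4 at -4.27 ± 0.83 and Usp18 at -2.81 ± 0.56 (camera adjusted p = 2.82e-08, adjusted p = 0.715 with an estimated correlation). Camera also called lower the red cell membrane list (4 of 21 genes; median -0.31) and the T cell markers (-0.97). It called higher the proteasome (4 of 31; 0.25), oxidative phosphorylation (6 of 28; 0.31) and ribosomal protein (2 of 84; 0.29) lists and the neutrophil markers (1.45; estimated-correlation adjusted p from 0.764 to 0.850 for these). Without wild type replicate 3 the red cell membrane (-0.07) and erythroid transcription factor (-0.26) calls ended, and without wild type replicate 1 the proteasome (0.13), T cell (-0.53) and neutrophil (1.51) calls. Leaving out double-null replicate 1, 2 or 3 kept 9, 8 and 9 of the 11 list calls, leaving out either miR-144/451-null replicate kept 10, and the term for sex kept 10, without the neutrophil markers (1.44) and with proteasome at 0.39 and ribosomal proteins at 0.50. Fry kept 5. The neutrophil call also ended with globin genes removed (1.48), and the red cell membrane median was -0.54 without wild type replicate 1. The replicate block kept 8 and ended the red cell membrane (-0.28), erythroid transcription factor (-0.40) and neutrophil (1.22) calls, while the T cell median moved to -1.55 (-1.64 without double-null replicate 2). B cell markers fell, 9 of 11 (median -2.08; camera adjusted p = 9.88e-06, adjusted p = 0.762 with an estimated correlation), and genes of B cells named by their size of change were Cr2 (14.7 ± 4.49 against 161 ± 78.9 CPM), Ms4a1, Spib and Cxcr5. With a term for sex the count was 560. It was 775 without wild type replicate 3, where 10 of 28 selected calls were lost, 964 without wild type replicate 1 and 1573 without double-null replicate 1, and the split was 803 higher and 1433 lower without scaling factors.

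The interaction, which tests whether loss of the cluster acted differently without Nrf2, called 9 genes, 4 higher and 5 lower. Apart from Fgfrl1 and Idua they lie outside the naming rule and were singled out after their values were seen. The cell cycle list lay further down without Nrf2 (median -0.38; camera adjusted p = 7.54e-07, adjusted p = 0.590 with an estimated correlation) and the proteasome list further up (median 0.28; camera adjusted p = 4.52e-07, adjusted p = 0.590 with an estimated correlation). No member of either passed edgeR's threshold, 5 cell cycle genes were lower and 4 proteasome genes higher at an unadjusted p under 0.05, and DESeq2 called 0 of each. With a term for sex the cell cycle call was kept (-0.60) and the proteasome call lost (0.01). The cell cycle median was -0.24 without double-null replicate 2, and the proteasome median 0.17 without wild type replicate 3, 0.18 without miR-144/451-null replicate 3 and 0.16 without scaling factors. Fry kept neither call. DESeq2 called 24 genes, a fit of all genes with a count 232, and the fit with a term for sex 2, Gm8730 and Fgfrl1. The count was 3 without wild type replicate 3 or miR-144/451-null replicate 1, 4 without wild type replicate 1, and 5 without Nrf2-null replicate 1, Nrf2-null replicate 2 or double-null replicate 1. Without scaling factors the split was 4 higher and 8 lower. The median of all genes shifted by 0.121 in miR-144/451-null against wild type when scaling factors were left out, by -0.104 in Nrf2-null against wild type, by -0.215 in double-null against miR-144/451-null and by -0.111 in the interaction. Under the scaling alternatives, the ribosomal protein list in double-null against miR-144/451-null was the sole list called by camera whose median changed sign.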

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

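The tests of sex, B cell content, neighbouring genes and shared reads were chosen after the results they bear on had been seen, and those of scaling, of library number and of other splits before.

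The effect of losing the cluster differed with and without Nrf2, by the interaction test in edgeR, for 9 genes. With a term for sex 2 were called, Gm8730 and Fgfrl1. Several of the 9 stood apart in 1 genotype. AA465934 was low in wild type alone (2.95 ± 0.314 CPM, against 16.8 ± 3.79 in Nrf2-null to 19.1 ± 1.97 in miR-144/451-null). Naip2 was low in miR-144/451-null alone (0.344 ± 0.177 CPM, against 7.13 ± 0.968 in double-null to 10.1 ± 1.88 in Nrf2-null). Gm8730, Gm9625, Fgfrl1 and Idua stood apart in Nrf2-null. The interaction log2 fold changes were -4.41 for Gm8730, -4.61 for Gm9625, 4.33 for Fgfrl1, 2.13 for Idua, 4.04 for Naip2, 8.44 for Naip5, -2.53 for AA465934, -8.07 for Cfap74 and -7.47 for 5830444B04Rik. The values above 7 in size are fitted values of genes with few counts. Gm9625 shares 50.9% of its 31-mers with Gm8730, Naip5 36.7% with Naip6 and Naip2 21.1% with Naip1, so their reads are uncertain. Naip5 had 157 counts over the wild type libraries and 0 over the miR-144/451-null libraries, at least 28-fold lower. Cfap74 had 150 counts in Nrf2-null and 1 in double-null, a ratio of 147 with a 95% counting interval from 26 to 5860. For 5830444B04Rik the counts were 99 and 1, a ratio of 97.2 with an interval from 17 to 3880.

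By camera, 11 lists also differed, with no member past edgeR's threshold and no call kept with an estimated correlation or by fry. With a term for sex 3 of the 11 calls were kept, 7 were lost and 1, ribosomal proteins, turned (-0.18), and the NK cell median, not called, became 1.03. The interferon-response call ended without miR-144/451-null replicate 1 (-0.24), the B cell call without miR-144/451-null replicate 3 (-0.31), wild type replicate 1 (-0.50) or double-null replicate 1 (-0.63), and the NK cell call without miR-144/451-null replicate 3 (-1.01). The Epo-Stat5 call ended without 5 of the libraries in turn and that of other antioxidant enzymes without 6. The replicate block ended the Epo-Stat5 call too (0.63). Without scaling factors the call of other antioxidant enzymes ended (0.10), and the medians were 0.16 for proteasome, 0.17 for oxidative phosphorylation and 0.13 for ribosomal proteins. Medians grew for macrophage markers with the term for sex (-3.30), NK cell markers without double-null replicate 2 (-2.15), Epo-Stat5 genes without Nrf2-null replicate 2 (0.85) and other antioxidant enzymes without miR-144/451-null replicate 1 (0.35). Without wild type replicate 1 the heat shock median was 0.08, without Nrf2-null replicate 3 the macrophage median was -0.74, the B cell median -0.51 and the ribosomal protein median 0.12, and without double-null replicate 3 the oxidative phosphorylation and ribosomal protein medians were 0.18 and 0.11. The medians of the interaction were -0.38 for cell cycle, 0.28 for proteasome, 0.43 for heat shock proteins, 0.28 for oxidative phosphorylation, 0.24 for ribosomal proteins, 0.53 for Epo-Stat5 response and survival, 0.22 for other antioxidant enzymes, -1.01 for interferon response, -0.84 for B cell markers, -1.41 for NK cell markers and -1.52 for macrophage and monocyte markers. At an unadjusted p under 0.05, 6 interferon-response genes were lower and 3 heat shock genes higher, and DESeq2 called 2 heat shock genes and 1 ribosomal protein gene. The sex-linked list also differed, since the sexes are not balanced across the genotypes.

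The cell cycle list lay lower in the libraries without the cluster. Sex of the animals is argued against for double-null against Nrf2-null, where the median was -0.95 in male libraries alone and lay between -1.23 and -0.75 in the 6 single pairs of male libraries. Of scaling, the TMM factors alone were examined, and without them the higher of the medians was -0.44. Leaving them out shifted the median of all genes by 0.121 in miR-144/451-null against wild type and by 0.01 in double-null against Nrf2-null. Shifts of this size could not have removed the fall, and scaling to library totals stayed in place. A change in RNA composition was therefore not tested. B cell markers summed to 2360 CPM in wild type and 2248 in Nrf2-null, so B cell transcripts remained after the isolation with beads. Loss of B cells is argued against, on the untested assumption that B cells hold few cell cycle transcripts per marker transcript. The list lost 11 times as many summed CPM as the 11 B cell markers in miR-144/451-null against wild type and 14.6 times in double-null against Nrf2-null. Of the abundant markers, Ighm stood at 514, 412, 510 and 363 CPM in wild type, miR-144/451-null, Nrf2-null and double-null, Cd74 at 531, 284, 520 and 153, and Igkc at 218, 254, 428 and 587. For miR-144/451-null against wild type, sex and genotype cannot be told apart: a term for sex gave -0.51, but it rests on 1 female double-null library. Fewer dividing erythroblasts on loss of the cluster is therefore a hypothesis that remains open, and no test here separates fewer cells in division from a different mix of maturation stages.

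Several genes called in a single genotype lie beside each other. The 9 interaction genes hold 3 pairs of near neighbours (Naip2 with Naip5, Cfap74 with 5830444B04Rik, and Fgfrl1 with Idua). The pairs were seen before they were counted, so their number is a description and no test of strain segments away from the targeted loci, which stay a hypothesis. Among the 200 tested genes nearest to Nfe2l2, 4 were called in Nrf2-null against wild type, an odds ratio of 12.3 (Fisher's exact test, two-sided p = 0.000534). In double-null against miR-144/451-null, where such a segment should differ too, 1 of them (Cwc22) was called, an odds ratio of 8.72 (Fisher's exact test, two-sided p = 0.121). These counts near Nfe2l2 were also chosen after the calls had been seen, so their p-values are a description too. A residual segment of another strain carried with the targeted Nfe2l2 allele may account for some calls near it, although the labels give a single strain. Calls near the miR-144/451 locus were not counted, so a segment carried with that allele was not examined. Reads shared with a copy may account for Gm8730: it shares 62.8% of its 31-mers with Rplp0, which stood at 698 ± 138 CPM in Nrf2-null against 1560 ± 7.07 in wild type. Their sum differed by -0.12 (log2), so the fall of Rplp0 in Nrf2-null could come from a sequence variant that moved its reads, and genotype effects on these genes were not tested apart from that.

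More genes passed the threshold on loss of the cluster without Nrf2 (3850) than with it (653). A larger number of libraries is argued against, since with 2 libraries per group the ratio of the counts was at least 3.1 in all 9 choices, with 1709 to 2857 calls without Nrf2 and 248 to 775 with it. What stays open is that the smaller comparison is also a comparison of sexes and rests on other libraries, and the interaction called 9 genes, so a larger effect without Nrf2 was not shown gene by gene. The 6 Nrf2-null and double-null libraries make 10 splits, too few for a share under 0.05. The real split gave 3850 calls and the highest of the others 0, and 1 split, the real one, gave as many. For the cell cycle list the real split gave a median of -0.92 and the farthest other split -0.43, with 1 of the 10 splits as far from 0.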

How the results depend on the processing

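The term for sex and the fit without X- and Y-linked genes were added after the data had been seen. Causes of the changes below were not tested, except that leaving out groups or libraries leaves fewer samples and that removing the filter admits genes with few counts. Double-null against Nrf2-null kept its count within 1.5 times of 3850 under the alternatives here, though with 2 libraries per group it was 1709 to 2857. The other counts moved as follows. With DESeq2, miR-144/451-null against wild type gave 1071 genes, Nrf2-null against wild type 134, double-null against miR-144/451-null 175 and the interaction 24. With all genes that have a count, the same comparisons gave 1254, 716, 743 and 232. In fits of the compared groups alone the first 3 gave 152, 45 and 2. With limma-voom, Nrf2-null against wild type gave 56, double-null against miR-144/451-null 3 and the interaction 4. With a term for sex, miR-144/451-null against wild type gave 1, Nrf2-null against wild type 12, double-null against wild type 560 and the interaction 2.

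Correlations of deviations from the group mean gave no clear sign that replicate numbers paired the libraries. The 13 same-numbered pairs correlated at -0.111 to 0.287 and 1 was over 0.1. The 24 other pairs correlated at -0.287 to 0.286 and 3 were over 0.1. In a group of 2 libraries the deviations mirror each other, so these values cannot exclude pairing. With a replicate block, miR-144/451-null against wild type gave 429 genes, double-null against miR-144/451-null 4 and the interaction 5, and the other counts stayed within 1.5 times. Of the 10 libraries 2 correlated best with their own number.

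Leaving out 1 library at a time gave 40 to 691 genes for miR-144/451-null against wild type, 11 to 32 for Nrf2-null against wild type, 4 to 78 for double-null against miR-144/451-null, 775 to 2648 for double-null against wild type and 3 to 12 for the interaction. Where this left a group with 1 library, that library was assumed to vary like the others. Of 147 calls of genes selected from the naming rule none changed sign, and 146 were kept with DESeq2, 139 without scaling factors, 122 with the replicate block, 91 without wild type replicate 3 and 82 with the term for sex. The share of carried-over signs stayed between 97.5% and 98.8%.

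With 8-mer sites the miR-451a difference lost its call in double-null against Nrf2-null (0.162) and double-null against wild type (0.276, adjusted p = 0.058). No list call was kept with an estimated correlation. In Nrf2-null against wild type, leaving out 1 library turned the medians of the red cell membrane list (-0.07 without wild type replicate 1; range -0.07 to 0.42) and of ribosomal proteins (0.01 without Nrf2-null replicate 3; range -0.19 to 0.01). The term for sex turned oxidative phosphorylation (0.02) and ribosomal proteins (0.22) there, and ribosomal proteins (-0.18) and NK cell markers (1.03) in the interaction. Without scaling factors ribosomal proteins turned in double-null against miR-144/451-null (-0.07). At this depth, 35 of 100 simulated 2-fold changes were recovered in miR-144/451-null against wild type.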

Other observations

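The sums of copies and the comparison of female libraries were chosen after the data had been seen. Some genes that differed between genotypes have near-identical copies, and they were summed with them. Rps19-ps6 stood at 59.9 ± 2.12 CPM in miR-144/451-null and at 8.76 ± 0.0636 in wild type, while Rps19 stood at 162 ± 13.4 and 217 ± 17, so that the sums were 222 ± 16.3 and 226 ± 16.3. Gm10031, which shares 93.3% of its 31-mers with the kinase gene Csnk2a1, stood at 41.5 ± 2.9 CPM in Nrf2-null and 12 ± 0.354 in wild type, and the sums were 137 ± 7.37 and 131 ± 9.9. Eif3j2 and Eif3j1 summed to 134 ± 3.21 CPM in Nrf2-null and 108 ± 1.41 in wild type, a difference larger than their spread.

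The female double-null library, replicate 3, can be set beside the female wild type libraries. Its cell cycle genes had median differences of -0.58 and -0.56 (log2 CPM) from wild type replicates 1 and 3, a comparison of single libraries without a test. The first principal component held 37.8% of the variance and placed the 5 libraries without the cluster between 9 and 64 and the other libraries between -61.6 and -28.6. Nrf2-null replicate 3 stood apart on the third component, at 38.8 against -25.1 and -31.7 for the other Nrf2-null libraries, and carried 1489 CPM of macrophage markers against 582 and 536.

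Camera called none of the heme, iron, globin, organelle clearance, progenitor, p53 target and glycolysis lists, nor the megakaryocyte, mast cell and endothelial markers, in miR-144/451-null against wild type, Nrf2-null against wild type or double-null against wild type. In miR-144/451-null against wild type their medians were -0.15, -0.26, -0.16, -0.01, -0.01, -0.01, 0.29, 0.06, 0.41 and -0.13. In double-null against Nrf2-null the globin list had a median of 0.15 and a mean of -0.56, and the Epo-Stat5 list -0.13 and 0.23, so that neither had a direction.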
